A study of Homo sapiens with 24 samples.

How the data were processed

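Ribosome profiling (Ribo-seq) sequences the mRNA fragments that ribosomes protect from nuclease, and RNA-seq in the same cells gives the RNA level. Both assays were run in parental MDA-MB-231 cells, LM2 cells, control guide cells and HNRNPC knockdown cells, with 3 replicates each. Per the labels' protocols, lysates contained cycloheximide, which holds ribosomes on mRNA, footprints were prepared by the method of McGlincy and Ingolia, RNA was isolated from the lysates, and RNA libraries were made with a SMARTer pico kit. Per the submitters' processing notes, cutadapt 2.3, UMI-tools, Bowtie2 2.3.5 and SAMtools were used with the hg38 genome build, with no role given for each. The transcript annotation, the rule for reads shared by transcripts of a gene or by near-identical genes, the scaling and any footprint correction are not given in the sources used here. Values of transcripts from overlapping or near-identical genes are therefore uncertain.

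The deposited values are a normalized read signal per transcript, 1 table per experiment, per the file headers and the values themselves, with 6 footprint and 6 RNA columns in each. The low RNA values in each library were whole multiples of 1 step (100% within 0.05 of a whole number of steps), as read counts divided by 1 factor per library would be. Higher RNA values were not checked for this. Footprint values had no common step and included exact zeros in 23 to 234 transcripts per library, so how the authors scaled or corrected them is unknown. No transcript had an RNA value under 5.10 in any library of the LM2 table or under 5.55 in the knockdown table, and no mean footprint value was under 2, so transcripts absent from the RNA of a group are outside the tables. No count model was run, since the footprint values are not counts and the RNA values lack the low counts. The parental columns of the LM2 table carry only the name of the line and were read as the parental samples of the same replicate number. All 24 columns of values were used.

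Values were transformed as log2(value + 1), on which changes of low values are understated. Transcripts with a mean of at least 10 over the 6 RNA libraries and at least 10 over the 6 footprint libraries of a table were tested. RNA and footprint changes were tested with limma 3.58.1 in R 4.3.3 (moderated variance with a trend on mean level) on the 6 libraries of an assay. The change in translation efficiency was tested as the interaction of assay and cell group in a limma model over the 12 libraries of a table. P-values were two-sided and adjusted by Benjamini-Hochberg over the transcripts tested, with a threshold of 0.05. All tests were made within a table, since the tables were normalized separately. The intervals of slopes came from 1000 bootstrap draws of transcripts. Overlaps were tested with Fisher's exact test, one-sided, adjusted over 12 overlaps. Correlations between the experiments were set against 100 pairs of regroupings, the 10 splits of the 6 replicates in one table by the 10 in the other, the real one included.

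The groups, tests, filters and most alternatives were fixed before the data were examined. The rule for named transcripts was HNRNPC, PABPC4 and PDLIM5 in every library, then the largest rises and falls among transcripts past the threshold whose groups do not overlap, for efficiency, RNA and footprints, and those called the same way in both experiments, all with a gene symbol. Of the 11396 transcript IDs, 0 matched the gene name tables used here, so that HNRNPC, PABPC4, PDLIM5 and the 37 gene lists fixed in advance were not analysed here, nor were 3' UTR length, coding length and GC content. At most 2 IDs that rose and 2 that fell are printed per experiment, by the same rule for efficiency, and the extreme RNA changes are given without an ID.

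Simulated data were drawn with the spread of the real libraries and errors independent between libraries. In them 200 transcripts were changed in footprints only and 200 others in RNA and footprints together. For the LM2 table (9342 transcripts) the efficiency test recovered 37.3%, 88.1% and 98.5% of log2 changes of 0.5, 1 and 2, with 4.49% of calls false. For the knockdown table (8283 transcripts) it recovered 23.9%, 70.2% and 100%, with 3.73% false. These false shares do not cover errors that libraries have in common. The RNA test recovered 91.0% and 94.0% of log2 changes of 0.5, and the footprint test 59.0% and 45.5%. Efficiency changes under 2-fold are thus often missed at this depth and number of replicates.

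Replicates were checked before averaging. No 2 columns were identical, and the chi-square per degree of freedom between RNA replicates of a group was 4.47 to 7.47. Alternatives were other pseudocounts, other filters, TMM scaling (own implementation), quantile normalization, the replicate number as a block, pairing of footprints and RNA by replicate number (a lysate block), no variance trend, array weights, the spread from all 12 libraries and leaving out each replicate. The lysate block was fitted on footprint minus RNA values, so its variance trend was on mean efficiency and not on mean level, with fewer degrees of freedom. Separate spreads per assay and a median change set to 0 were added after the data were seen, as were ranked lists of regrouped replicates, each as long as the real list of lower calls and ranked by limma's moderated statistic, and 10000 redraws of the knockdown calls within 25 strata of footprint and RNA level for the footprint and RNA overlaps.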

Results

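Ribosome footprints and RNA were sequenced in 4 groups of MDA-MB-231 cells, a human breast cancer line, with 3 replicates per group and assay and 24 libraries in all. In the first experiment, LM2 cells, a derivative labelled as highly metastatic to the lungs, were set against the poorly metastatic parental line. In the other experiment, cells labelled as an HNRNPC knockdown (sgHNRNPC) were set against cells with a control guide (sgCTRL). HNRNPC is a nuclear protein that binds pre-mRNA. The stated purpose was to compare translation efficiency, here the footprint value per RNA value of a transcript, between these cells. The deposited tables list transcripts by Ensembl transcript ID and do not pair them with gene names, so HNRNPC itself and gene groups were not analysed here, and transcripts are described by how their RNA, footprints and efficiency moved.

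The LM2 table held 11252 transcripts, of which 9342 were tested, and the knockdown table held 10767, of which 8283 were tested. The RNA values corresponded to about 26800000 to 52600000 reads per library over the listed transcripts in the LM2 table and to about 23300000 to 28300000 in the knockdown table. Footprint values summed to 1023095 to 1134509 per library in the LM2 table and to 669584 to 753066 in the knockdown table, and the footprint depth in reads is unknown. The median tested transcript had a mean footprint value of 63.5 in the LM2 table and 47.9 in the knockdown table. Replicates had a median SD of 0.07 on the log2 scale for RNA in all 4 cell groups, against 0.14 in LM2 cells, 0.16 in parental cells, 0.18 in control guide cells and 0.17 in knockdown cells for footprints. No pair of columns was identical, and RNA replicates differed by more than sampling noise. The labels do not say whether replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.

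LM2 cells differed from parental cells in the RNA of 5017 transcripts and in the translation efficiency of 152. RNA rose for 2142 transcripts and fell for 2875 of 9342, footprints rose for 864 and fell for 1359, and efficiency rose for 44 and fell for 108. Among transcripts whose RNA rose, footprints also rose for 710 (33.1%) and fell for 44, and among those whose RNA fell, footprints also fell for 1136 (39.5%) and rose for 4. Footprints moved the same way as RNA in the extreme RNA changes. The transcript with the largest RNA fall had an RNA value of 119 ± 23.5 in LM2 cells and 11640 ± 272 in parental cells (SD, n = 3), and a footprint value of 4.94 ± 2.90 against 486 ± 41.2. The transcript with the largest RNA rise went from an RNA value of 21.7 ± 12.2 in parental cells to 752 ± 36.3 in LM2 cells, with footprints of 3.40 ± 2.03 and 74.3 ± 2.35. The efficiency change was 0.118 for the largest RNA fall and -1.02 for the largest RNA rise on the log2 scale, and neither passed the test (limma, adjusted p = 0.926 and 0.459). Footprints were low in the lower group of each, so a test not passed does not show that efficiency was unchanged. The tests differed in sensitivity, since on simulated data the RNA test recovered 91.0% and the efficiency test 37.3% of log2 changes of 0.5. Far fewer transcripts were changed in the simulation than were called for RNA here, so these shares are not those of the real tests.

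Footprints fell for 70 of the 108 transcripts whose efficiency fell in LM2 cells. RNA of the 108 rose for 71, fell for 13 and did not pass the test for 24. In 33 of them RNA rose and footprints fell. Of the 44 whose efficiency rose, RNA fell for 32, footprints rose for 15, and footprints did not pass the test for 19. An efficiency change holds the RNA change with the opposite sign, so RNA error alone favours opposite moves of efficiency and RNA. It holds the footprint change with the same sign, so footprint error favours efficiency and footprints moving together. Footprint error was the larger, with a median SE of 0.15 against 0.07 for RNA. Changes were moderate, with a median size of 0.51 on the log2 scale among the 152 calls and 13 calls beyond 2-fold.

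ENST00000388948 had the largest efficiency rise among the transcripts past the threshold, 1.43 ± 0.22 (log2 change ± SE, limma adjusted p = 0.00193), with footprints of 47.0 ± 2.64 in LM2 cells and 20.1 ± 7.74 in parental cells (SD, n = 3) at RNA values of 13450 ± 163 and 15170 ± 67.3. ENST00000262942 rose by 1.29 ± 0.10 (adjusted p = 3.47e-07), where its RNA fell from 9832 ± 361 to 6011 ± 64.8 and its footprints rose from 169 ± 12.4 to 254 ± 19.3. ENST00000373218 fell by 1.60 ± 0.24 (adjusted p = 0.00142), where its RNA rose from 5703 ± 126 to 10250 ± 192 and its footprints fell from 40.2 ± 14.8 to 22.8 ± 5.12. ENST00000303375 fell by 1.47 ± 0.36 (adjusted p = 0.0438), with footprints of 6.39 ± 1.81 in LM2 cells and 15.2 ± 1.96 in parental cells.

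The number of efficiency calls changed with how the spread was estimated and with leaving out a replicate. The count of 152 became 18 without a variance trend, 43 with the replicate number as a block and 311 with array weights. When each replicate's footprints were paired with the RNA of the same number, as if from a shared lysate, limma called 0 transcripts (1078 at an unadjusted p under 0.05), and the adjusted p was 0.191, 0.059, 0.191 and 0.191 for the 4 named transcripts in the order above. That fit also had another variance trend, on mean efficiency, and fewer degrees of freedom, so the loss cannot be put down to pairing alone. The count was 35, 63 and 49 without parental replicate 1, 2 and 3, and 310, 25 and 31 without LM2 replicate 1, 2 and 3. A fit without a replicate has fewer degrees of freedom, so a lower count does not alone show reliance on that replicate. Without a variance trend, ENST00000388948 (adjusted p = 0.0589), ENST00000373218 (0.0531) and ENST00000303375 (0.0862) also missed the threshold. ENST00000303375 was past the threshold in 6 of 17 alternatives and in none of those that left out a replicate. The share of efficiency calls that were higher was 28.9% as deposited and 15.9% with the median change set to 0. It was 26.4% after TMM scaling and 37.4% (73 higher and 122 lower) after quantile normalization. Quantile normalization turned the balance of RNA calls, with 51.8% higher against 42.7% as deposited. With the spread taken from all 12 libraries, 2701 RNA changes passed, against 5017.

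**Figure D1:**
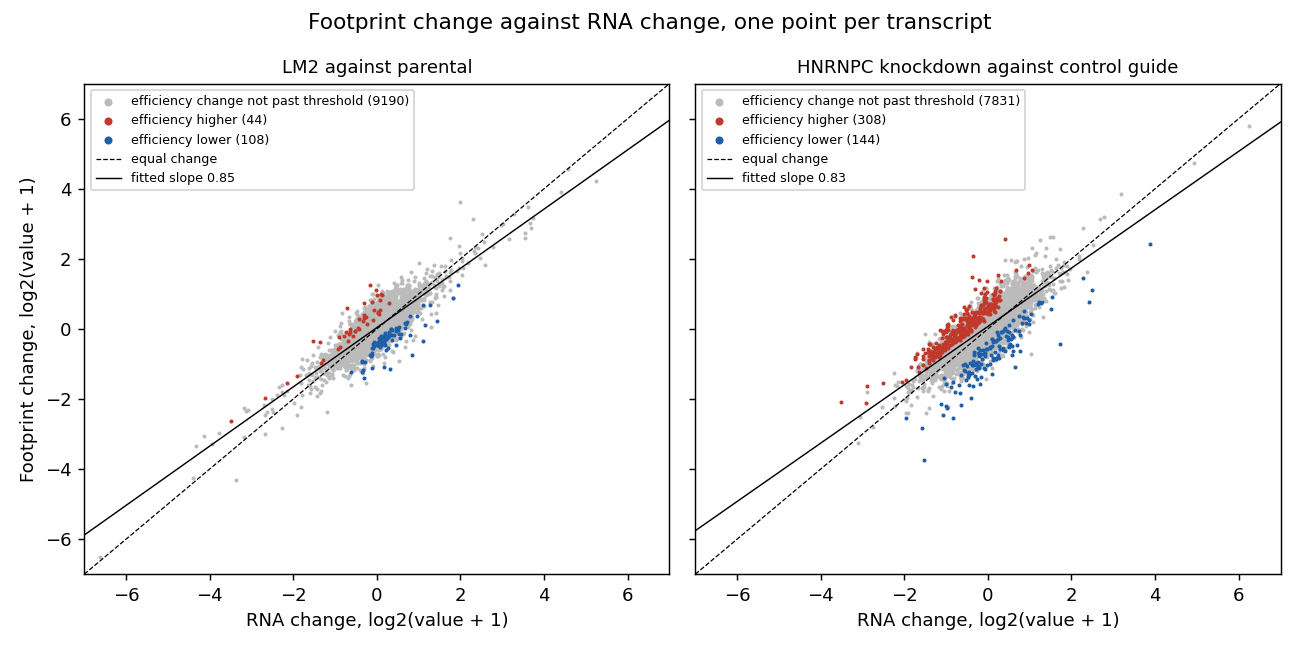
Log2 change in RNA (x axis) against log2 change in footprints (y axis) of each tested transcript, LM2 against parental on the left and HNRNPC knockdown against control guide on the right. Coloured points passed the test for translation efficiency (44 higher and 108 lower on the left, 308 higher and 144 lower on the right, as deposited; after TMM scaling the counts on the right were 153 higher and 199 lower), the dashed line marks equal change, and the solid line is the fitted slope of 0.85 and 0.83.

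HNRNPC knockdown cells differed from control guide cells in the RNA of 6084 transcripts and in the translation efficiency of 452. RNA rose for 2323 transcripts and fell for 3761 of 8283, footprints rose for 1286 and fell for 1712, and efficiency rose for 308 and fell for 144. Among transcripts whose RNA rose, footprints also rose for 1103 (47.5%) and fell for 21, and among those whose RNA fell, footprints also fell for 1593 (42.4%) and rose for 19. RNA falls beyond 2-fold outnumbered rises, with 464 against 180 as deposited and 317 against 243 after quantile normalization. The transcript with the largest RNA rise had an RNA value of 1093 ± 44.7 in knockdown cells and 13.5 ± 1.95 in control guide cells, and a footprint value of 66.9 ± 1.98 against 0.275 ± 0.476. The transcript with the largest RNA fall had an RNA value of 330.1 ± 37.2 against 3788 ± 67.4 and a footprint value of 13.95 ± 6.89 against 59.9 ± 16.1, so that its efficiency rose by 1.43 (limma, adjusted p = 0.0246).

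Of the 308 transcripts whose efficiency rose in the knockdown cells, RNA fell for 240. Among those 240, footprints fell for 81, rose for 14 and did not pass the test for 145, and the footprint change was smaller in size than the RNA change in 210. That size is fixed in part by arithmetic. Where efficiency rises and RNA falls, the footprint change can be the larger only if footprints rise by more than RNA falls. In 29 others both RNA and footprints rose, and in 35 footprints rose while RNA did not pass the test. Of the 144 whose efficiency fell, footprints fell for 95, RNA rose for 70 and RNA fell for 52. In those 52 footprints passed the test for a fall as well. They fell by more than the RNA, as a fall in efficiency together with a fall in RNA requires. These classes were taken on values as deposited and were not rerun under other scalings. The direction of the balance of efficiency calls depended on scaling. As deposited, 68.1% of the efficiency calls were higher, against 43.5% (153 higher and 199 lower) after TMM scaling, 41.8% after quantile normalization and 37.3% (123 and 207) with the median change set to 0. The median RNA change was -0.10 on the log2 scale as deposited and 0.01 after quantile normalization, and the share of RNA calls that were higher was 38.2% and 51.3%.

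ENST00000332127 had the largest efficiency rise of the transcripts past the threshold, 2.42 ± 0.19 (log2 change ± SE, limma adjusted p = 2.31e-06), with footprints of 63.7 ± 2.58 in knockdown cells and 14.7 ± 3.84 in control guide cells (SD, n = 3) while its RNA fell from 3148 ± 26.8 to 2470 ± 40.3. ENST00000310473 rose by 2.17 ± 0.23 (adjusted p = 5.12e-05), with footprints of 34.6 ± 3.43 against 5.03 ± 1.39 and RNA of 2109 ± 75.5 against 1599 ± 187. ENST00000331079 fell by 2.21 ± 0.33 (adjusted p = 0.000976), where RNA fell from 632 ± 19.2 to 217 ± 7.94 and footprints fell further, from 40.6 ± 5.12 to 2.22 ± 1.16. ENST00000322941 fell by 2.15 ± 0.39 (adjusted p = 0.00488), where RNA rose from 43.4 ± 16.5 to 140 ± 17.1 and footprints of 10.7 ± 2.40 and 14.8 ± 3.01 did not pass the test (adjusted p = 0.327). These 4 were past the threshold in all 17 alternatives run on them, but the change of ENST00000331079, whose knockdown footprints were low, ranged from -1.15 with a pseudocount of 5 to -2.82 after quantile normalization, and that of ENST00000310473 was 1.58 with a pseudocount of 5. The fit that paired footprints and RNA by replicate number, with its other variance trend, left 75 calls, 36 higher and 39 lower. The count of 452 was 249, 182 and 256 without control guide replicate 1, 2 and 3, and 178 and 200 without knockdown replicate 2 and 3.

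**Figure D2:**
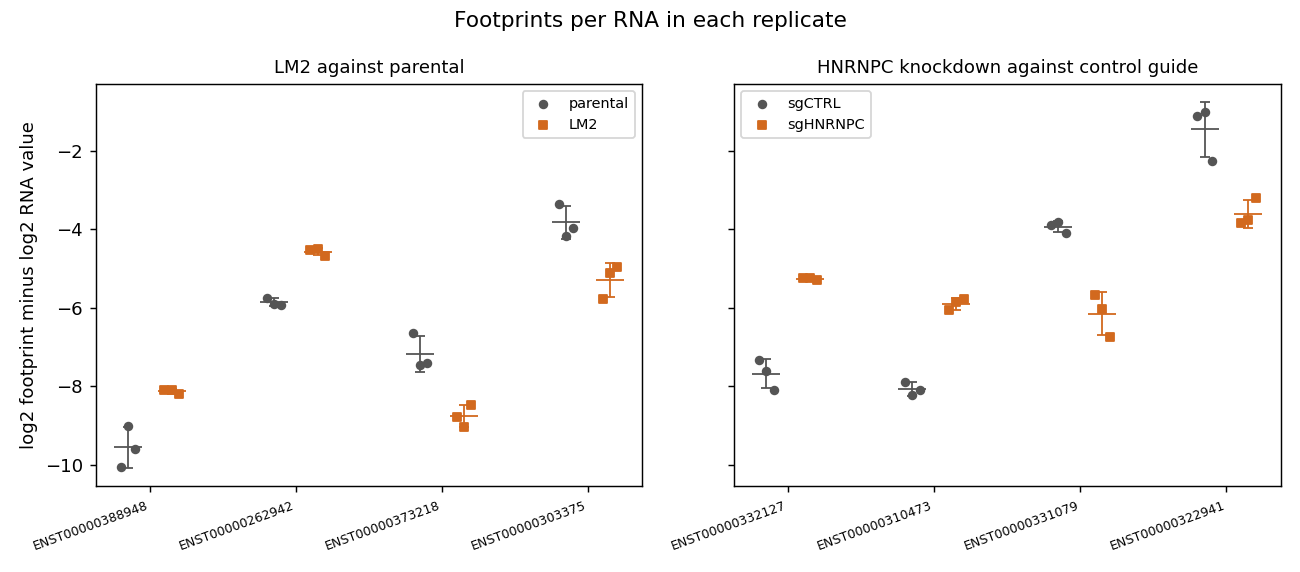
Log2 footprint value minus log2 RNA value (y axis) in each of 3 replicates per group for the 8 named transcripts, with horizontal bars for the group mean and error bars for the SD. In every transcript shown the replicates of the compared groups do not overlap, which was part of the rule that chose them.

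Footprint and RNA changes moved together in both experiments. Across transcripts, which are not independent replicates, the slope of footprint change on RNA change was 0.85 in LM2 cells (95% bootstrap interval 0.83 to 0.86, Pearson r = 0.83) and 0.83 in knockdown cells (0.82 to 0.85, r = 0.82). Among transcripts with a mean footprint value of at least 200 it was 0.743 and 0.699. With the RNA change of the other replicates as an instrument against RNA error it was 0.891 and 0.855. The slope of RNA change on footprint change was also below 1, at 0.82 and 0.80, but error in the footprint change lowers it. The SD of footprint changes was 0.45 in LM2 cells and 0.57 in knockdown cells, and that of RNA changes 0.45 and 0.56. Footprint changes held more error, with a median SE of 0.15 and 0.17 against 0.07 for RNA in both experiments. Like SDs therefore do not show that the changes were of like size.

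The tables have no library in common, and 8171 transcripts were tested in both. Efficiency was lower in both for 16 transcripts, where independent lists of 106 and 142 would share 1.84 (one-sided Fisher's exact test, p = 2.87e-11, adjusted over 12 overlaps 1.72e-10). That test takes transcripts as independent. Ranked lists of the same lengths from regrouped replicates shared up to 14, with a median of 4 and 3 pairs that shared at least 10. Each of those pairs was scored in the pairing of directions that shared most, and the real pair for lower in both only. The 16 had a median efficiency change of -0.66 in LM2 cells and -0.70 in knockdown cells, and footprints fell in both for 11 of them. Their RNA went either way, rising for 8 and falling for 5 in LM2 cells and rising for 6 and falling for 7 in knockdown cells. ENST00000373218 was among them, with a change of -1.60 in LM2 cells and -1.18 in knockdown cells. Efficiency was higher in both for 3 transcripts, against 1.5 for independent lists (adjusted p = 0.322), and moved in opposite directions for 5, all lower in LM2 cells and higher in knockdown cells. The footprint and RNA overlaps that follow were taken on values as deposited and were not rerun under other scalings. Quantile normalization moved the balance of RNA calls in both experiments. Footprints fell in both for 396 transcripts, against 264 for independent lists (adjusted p = 1.72e-20). RNA fell in both for 1268, against 1190 (adjusted p = 0.00063), and rose in LM2 cells while it fell in knockdown cells for 929, against 838 (adjusted p = 3.16e-06). When the knockdown calls were redrawn among transcripts of like footprint and RNA level, the 95% range of draws was 302 to 354 for footprints that fell in both, 1202 to 1282 for RNA that fell in both, which holds the 1268, 682 to 754 for RNA that fell in LM2 cells and rose in knockdown cells, where 755 did against 727 for independent lists (adjusted p = 0.146), and 813 to 886 for RNA that rose in LM2 cells and fell in knockdown cells. The other footprint and RNA overlaps did not pass the one-sided test for more, among them RNA that rose in both for 434 transcripts, against 511 (476 to 541 in the draws), and footprints that rose in both for 102, against 116 (97 to 134).

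Over all 8171 transcripts the efficiency changes of the 2 experiments were not correlated beyond what regrouped replicates gave. Regroupings keep a part of the real differences between groups, so they are not a reference of replicate noise alone. Spearman's rho was 0.03 and Pearson's r was 0.04, and 51 and 26 of 100 pairs of regroupings gave a value as large (adjusted over 3 readouts, p = 0.95 and 0.69). For RNA, rho was -0.0033 and r was 0.04 (95 and 46 of 100, adjusted p = 0.95 and 0.69). For footprints, rho was 0.01 and r was 0.0085 (79 and 88 of 100, adjusted p = 0.95 and 0.88). The fit that paired footprints and RNA by replicate number, with its other variance trend, left 0 shared transcripts, since limma then called 0 in LM2 cells (1078 at an unadjusted p under 0.05). The 16 became 6 without parental replicate 1, 10 without parental replicate 3, 6 and 8 without LM2 replicate 2 and 3, 8, 7 and 10 without control guide replicate 1, 2 and 3, and 8 without knockdown replicate 2.

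**Figure D3:**
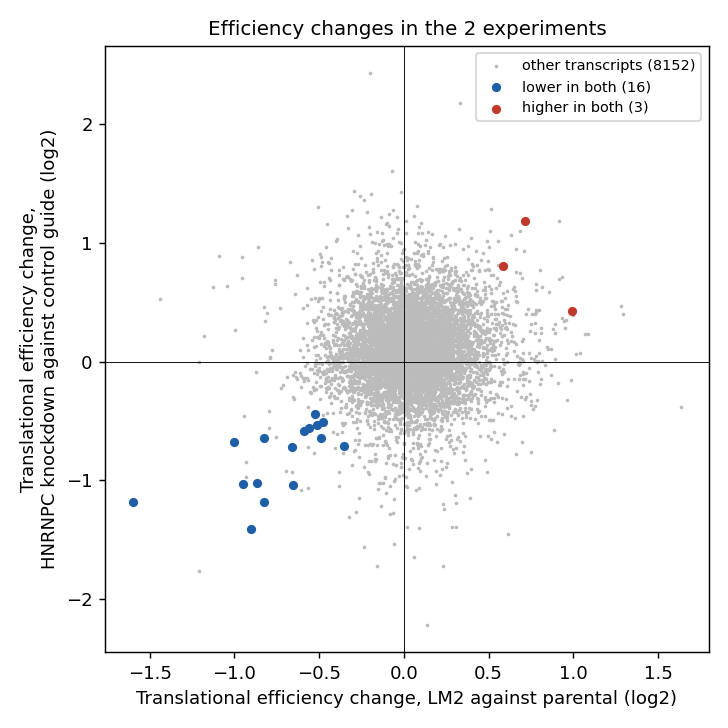
Log2 change in translation efficiency in LM2 against parental cells (x axis) and in HNRNPC knockdown against control guide cells (y axis) for the 8171 transcripts tested in both, as deposited. The 16 transcripts lower in both are blue, the 3 higher in both are red, and the cloud of other transcripts has no slope that stands out from regrouped replicates.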

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

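Separate spreads, median-centred changes, all scalings and blocks of the count lower in both experiments and the scalings of the most abundant transcripts were chosen after the data were seen; the other alternatives were planned. Total RNA and footprint counts stayed within 1.5 times the reported count except those given here. With a minimum mean of 50, fewer transcripts were tested, and 3156 (LM2) and 3101 (knockdown) RNA changes and 1844 (knockdown) footprint changes passed, and 550 footprint rises in LM2 cells. With the spread taken from all 12 libraries, LM2 cells had 3434 footprint and 2701 RNA changes, and knockdown cells 1425 RNA rises. Without a variance trend, 1173 footprint and 18 efficiency changes passed in LM2 cells and 244 efficiency changes in knockdown cells. Array weights gave 311 efficiency changes in LM2 cells. The replicate block gave 43 (LM2) and 183 (knockdown) efficiency changes and 8 lower in both. The numbers are not shown to pair samples, since deviations of same-numbered samples correlated from -0.195 to 0.0349 and from -0.106 to 0.0198, and the block moved no RNA or footprint count by over 1.5 times. The lysate block gave 0 (limma, 1078 at an unadjusted p under 0.05) in LM2 cells, 75 in knockdown cells and 0 lower in both. It recovered 73.1% and 46.3% of simulated log2 changes of 1, and same-numbered footprints and RNA correlated from -0.0061 to 0.113 and from 0.0112 to 0.126. The variance trend of the lysate block was on mean efficiency, and its degrees of freedom were fewer, so its loss of calls cannot be put down to pairing alone. Leaving out 1 replicate gave 25 to 310 efficiency changes in LM2 cells (35, 63 and 49 without parental replicate 1, 2 and 3, 310, 25 and 31 without LM2 replicate 1, 2 and 3) and 178 to 370 in knockdown cells (249, 182 and 256 without control guide replicate 1, 2 and 3, 178 and 200 without knockdown replicate 2 and 3). The 864 footprint rises in LM2 cells became 548 and 541 without LM2 replicate 2 and 3. Leaving out 1 replicate left 6 to 17 lower in both (6 and 10 without parental replicate 1 and 3, 6 and 8 without LM2 replicate 2 and 3, 8, 7 and 10 without control guide replicate 1, 2 and 3, 8 without knockdown replicate 2), and Fisher's exact p was at most 2.82e-05. TMM, quantile normalization and median-centring gave 17, 20 and 20 lower in both. No call was gained for the correlation of efficiency changes (rho 0.0061 to 0.063). The slope of footprint on RNA change was 0.73 and 0.72 with a pseudocount of 5 and 0.87 and 0.85 with 0.5. Beyond the mean filter, which tested fewer transcripts, the cause was not tested. Count models, gene list tests and tests of UTR length, coding length and GC content were not run. The footprint depth in reads is unknown, and its effect was not measured.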

Other observations

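The tests in this paragraph and the next, and the test on ranked lists after them, were chosen after the results were seen, and the other tests were written before. Of the 108 transcripts whose efficiency fell in LM2 cells, 68 lay in the top 10% of transcripts by RNA level, as did 10 of the 44 whose efficiency rose. In knockdown cells the top 10% held 32 of the 144 whose efficiency fell and 53 of the 308 whose efficiency rose, and its median efficiency change was 0.03, against -0.06 in LM2 cells. Over all tested transcripts the median was 0.09 in knockdown cells and 0.04 in LM2 cells, so the top 10% lay below it in both experiments. Among the 935 transcripts of the top 10% in the LM2 experiment the median footprint change was -0.18 on the log2 scale and the median RNA change -0.05, against 0.04 and -0.03 in the lowest 10%. Footprints of the top 10%, relative to the other transcripts, stood at -0.11, -0.22 and -0.26 in the 3 LM2 replicates and at -0.0059, -0.04 and 0.03 in the parental ones. The difference of -0.20 could not pass a threshold of 0.05 in an exact permutation test (two-sided, p = 0.1, the smallest that 3 against 3 can give). It was -0.20 after TMM scaling and -0.02 (exact p = 0.4) after quantile normalization, which gives all libraries 1 distribution and so removes such a difference in part by construction. In knockdown cells the footprint difference was -0.13 as deposited (exact p = 0.2) and -0.05 after quantile normalization (exact p = 0.1). The RNA difference was -0.04 in LM2 cells and -0.07 in knockdown cells (exact p = 0.1 for both), and 0.01 (exact p = 0.1) and 0.0034 (exact p = 0.6) after quantile normalization. The power of the test was not compared between RNA levels, so the place of the calls alone does not show where changes were largest.

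Of the 142 transcripts whose efficiency fell in knockdown cells, 126 passed no threshold in LM2 cells. Their median change there was -0.02, where all transcripts had 0.04, and 80 (63.5%) lay below that median. The list stood at percentile 1.6 of 10000 random lists matched on footprint level. Of the 106 that fell in LM2 cells, 85 passed no threshold in knockdown cells, where their median was -0.03 against 0.09 for all transcripts, with 60 (70.6%) below it (percentile 0.4). Of those that rose, the 298 from knockdown cells that were not called in LM2 cells had a median of 0.04 there (percentile 64.3), and the 37 from LM2 cells not called in knockdown cells had 0.11 (percentile 70.3). With transcripts called in both kept, the 40 rises of LM2 cells had a median of 0.175 in knockdown cells (percentile 97.1). The 306 rises of knockdown cells had 0.03 in LM2 cells (percentile 56.85). The full lists of falls stood at percentile 0 (LM2) and 0.01 (knockdown). Transcripts are not independent, so the percentiles describe these libraries.

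The 16 transcripts lower in both experiments were set against 2 technical explanations. If abundance alone made the same transcripts callable, redrawing the knockdown calls within 25 strata of footprint and RNA level would share as many, but the draws shared 2.72 on average (95% range 0 to 6) and p was 1e-04, the smallest that 10000 draws can give. Replicate noise common to both tables stays open. Regroupings other than the real one gave no calls to share, so that 1 of the 100 pairs, the real one, sharing as many decides nothing. On ranked lists of 106 and 142 transcripts 1 of the 100 pairs, again the real one, shared 16, and the highest other shared 14. That gap is within the counting spread of 4, and the median of the other pairs was 4. The scores are not alike. Each other pair took its best pairing of directions, and the real pair that of lower in both. Footprint correction by the authors, isoforms that share reads, culture differences and an effect common to LM2 cells and HNRNPC knockdown were not tested, and with the lysate block 0 were shared.

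Both slopes lay below 1. That of RNA change on footprint change, 0.82 and 0.80, is lowered by error in the footprint change (median SE 0.15 and 0.17, against 0.07 for RNA). That of footprint change on RNA change was 0.85 and 0.83, which alone does not show that footprints changed less. If low footprint values and the pseudocount were the whole cause, the slope would be at least 0.95 among transcripts with a mean footprint value of at least 200, but it was 0.743 (95% interval 0.642 to 0.83, 1378 transcripts) in LM2 cells and 0.699 (0.669 to 0.73, 762 transcripts) in knockdown cells. If error in the RNA change were the whole cause, using the other replicates' RNA change as an instrument would bring the slope to at least 0.95, but it was 0.891 (0.873 to 0.908) and 0.855 (0.839 to 0.871). These were above 0.846 and 0.833, so RNA error may account for a part. The authors' scaling or correction of footprints stays open, and no biological explanation was tested.

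The 6 replicates of an experiment can be split 3 against 3 in 10 ways, too few for a share under 0.05. In each of the 6 counts of calls, 1 of the 10 splits, the real one, gave as many. In LM2 cells the real counts were 152 for efficiency, 2223 for footprints and 5017 for RNA, and in knockdown cells 452, 2998 and 6084, and the highest count of any other split was 0 in each (limma). At an unadjusted p under 0.05, other splits gave at most 269, 335 and 169 transcripts in the LM2 table and 139, 245 and 31 in the knockdown table. Every other split puts samples of both cell groups on each side, so a real difference raises its spread and lowers its count. The counts of the other splits are therefore no measure of what replicate noise alone would give.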
